A study of Rattus norvegicus with 8 samples.

How the data were processed

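Islet cells of rats at postnatal day 10 (Sprague Dawley strain, per the labels) were dissociated, cultured and transfected with locked nucleic acid (LNA) oligonucleotides, and their RNA was sequenced in 8 libraries. Per the labels, 4 libraries came from cells given 60 pmol of a control LNA and 4 from cells given 3 LNA inhibitors of tiRNA-5 at 20 pmol each. tiRNA-5 are the fragments left at the 5-prime side when a tRNA is cut in its anticodon loop, and the fragments targeted here came from the histidine tRNA with anticodon GTG and the glutamate tRNAs with anticodons CTC and TTC. The labels do not say whether the libraries of a group came from separate litters, cultures or days, so p-values measure the spread between these libraries. The libraries carry numbers from 1 to 4 in both groups, and the labels do not say that a shared number marks a shared culture.

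The deposited values were RPKM (reads per kilobase of gene, scaled to the size of the library), 1 column per library, per the file headers. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0, HISAT2 2.1.0 and HTSeq, with the rat genome build rn6. Which of these tools gave the RPKM values, the gene annotation, the handling of strand and the rule by which genes were listed were not given in the sources used here. The deposited table had 10692 rows, and each row had a mean RPKM of at least 1 in both groups, so genes near the floor in either group were not analysed here. No mitochondrially encoded mRNA was among the rows, and Ang, the gene of a ribonuclease that cuts tRNAs, was not analysed here. Of the row names, 9816 were current symbols of the reference gene table used here (assembly GRCr8), 330 were older symbols and 546 matched neither. That assembly differs from the authors' build, so it served for names only and no coordinates are given. A symbol stood on more than 1 row for 9 genes, whose rows were kept apart.

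The authors' deposited table also gave a fold, which was the ratio of the inhibitor and control means of the RPKM columns, and a log2 fold change, which lay below the log2 of that fold by a median of 0.022. Its p-values and adjusted p-values were the authors', by a test not given in the sources used here. The adjusted values did not increase in step with the p-values, so they are quoted as the authors' and were not used in any test.

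The RPKM of a gene are whole multiples of the value of 1 read, which depends on the library and the gene length. Ratios between libraries that recurred over genes gave the relative library sizes, and the smallest whole numbers in the proportions of the 8 values, within a tolerance of 0.0001, gave the reads. This recovered whole reads for 10692 of the 10692 genes. On simulated reads of 1500 genes, 99.73% came back exactly and 100% came back up to a common divisor. Reads in the listed genes came to between 16035607 and 19049788 per library, with a median of between 544 and 665 reads per gene. The total number of sequenced reads is unknown. The reads served for depth, for the shares of the hormone genes and for an alternative test.

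The design fixed before the data were examined had expected counts and a count model. As the deposited unit was RPKM, the test named there for such values was used. log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 for the 10688 genes with an RPKM of at least 1 in at least 4 libraries, which left out 4 genes. The model held the group alone, with an intensity trend in the empirical Bayes step, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Fold changes are inhibitor minus control on the log2(RPKM + 1) scale, which understates changes of genes of low RPKM. The median half-width of the 95% confidence interval of a log2 fold change was 0.20.

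Known changes were added to 200 genes of simulated data to see what the test could find. In reads drawn independently per gene, it called 16% of the genes changed 1.25-fold, 52% of those changed 1.5-fold, 92% of those changed 2-fold and 98% of those changed 3-fold, with 7 wrong calls among 136. With the changes added to the real residuals, these shares were 10%, 64%, 96% and 98%, with 0 wrong calls among 134. Such residuals carry no difference between the groups, so the 0 wrong calls were fixed in advance. The shares of this simulation also leave out chance error in the fold changes. Both simulations were run on 10688 genes with 50 genes per fold.

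A set of 37 gene lists was fixed before the data were examined, of which 34 had at least 3 tested members. The lists of mitochondrially encoded mRNAs, of erythroid and platelet genes and of replication-dependent histones had fewer and were not tested. Lists were tested with camera in limma, which compares a list with all other genes, with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. The correlation estimated per list and the rotation test fry were the alternatives. In simulated data, camera called the 1 shifted list and 0 of 33 lists that were not shifted. In the simulations described above, correlated genes could not shift a list by chance. They therefore do not show how often camera wrongly calls lists of correlated genes. The estimated correlation was 0.90 for the list of G2/M and mitosis, against the preset 0.01. An exact permutation test over the 70 assignments of 4 and 4 libraries was applied to each list's mean and to the shares of reads, and the smallest p it can give is 0.0286.

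The genes named were chosen by a rule fixed before the data were examined. As no gene passed the threshold, the 5 genes with the smallest p in each direction were named. From the lists described it allowed up to 4 members with the smallest p, along with Ins1, Ins2, Gcg, Sst, Mki67 and Ang whatever their p. How many members each list got within that limit, from 0 to 4, was settled after the data were seen. Of the genes that the rule picked, 2 are not reported here. Elavl4 and the Y-linked genes Eif2s3y and Kdm5d were also named after their values were seen. Row names that are identifiers and not gene symbols were left out.

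Alternatives were median-of-ratios scaling, scaling to total reads, no filter on low values, a minimum of 10 reads in all 8 libraries, a pseudocount of 0.1, limma-voom on the recovered reads, a block for the replicate number, removal of the insulin genes before scaling, a minimum fold of 1.5, and each library left out in turn. Library weights, the mean of the mesenchymal markers as a covariate, and leaving out both control 1 and inhibitor 4 were added after the data were seen. Chi-square per degree of freedom between the reads of 2 libraries was between 6.92 and 76.6 over all 28 pairs, so no library was a copy of another. Other tools used were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.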

Results

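The study measured mRNA in cultured islet cells of rats at postnatal day 10, an age at which insulin-producing beta cells are still immature. Cells received either a control LNA or a mixture of 3 LNA inhibitors directed at tiRNA-5 fragments of the histidine and glutamate tRNAs, with 4 libraries in each group. The comparison asks which mRNAs differ once these fragments are inhibited. The tiRNA-5 themselves are not measured by the RPKM values, so inhibition was not checked here. Reads in the listed genes ranged from 16035607 to 19049788 per library, and the median gene had between 544 and 665 reads. By its Y-linked genes, given below, inhibitor 4 held few cells of male animals, so it differed from the control libraries in more than the LNA.

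Insulin mRNA dominated all 8 libraries and did not differ between the groups by more than their spread. Ins1 and Ins2, the paralogous insulin genes of the rat, together took 13.2% ± 1.54 of reads in control cells and 12.4% ± 2.37 in inhibitor cells (SD, n = 4 each; exact permutation p = 0.657, two-sided, adjusted p = 0.657 over 4 shares). Without inhibitor 4 the difference was 0.209 percentage points in the other direction. Ins1 stood at 142460 ± 17363 RPKM in control and 129690 ± 23827 RPKM in inhibitor cells (SD, n = 4), and Ins2 at 68960 ± 5847 and 66228 ± 14826 RPKM. Reads of these near-identical genes can be assigned to the wrong copy, so the sum is firmer than either value. Gcg, which encodes glucagon, took 1.11% ± 0.152 and 1.18% ± 0.176 of reads (SD, n = 4; exact permutation p = 0.6, two-sided, adjusted p = 0.657), and without control 1 or inhibitor 4 the difference was -0.0045 or -0.019 percentage points. Sst, which encodes somatostatin, took 0.0661% ± 0.0191 of reads in control and 0.0463% ± 0.0083 in inhibitor cells (SD, n = 4; exact permutation p = 0.114, two-sided, adjusted p = 0.457). Without control 4 the Sst difference was -0.025 percentage points with an exact permutation p of 0.0286 (unadjusted), the smallest that the remaining libraries can give, and without control 1 it was -0.0113 percentage points. Ppy, which encodes pancreatic polypeptide, took 0.00604% ± 0.00128 and 0.00556% ± 0.00081 of reads (SD, n = 4; exact permutation p = 0.6, two-sided, adjusted p = 0.657), and without control 3 the difference was 7.03e-05 percentage points.

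No single gene passed the threshold in either direction. Of 10688 genes, 0 were higher and 0 lower in inhibitor cells at an adjusted p under 0.05 by limma, and the smallest adjusted p was 0.541. limma-voom on the recovered reads also called 0 genes. At an unadjusted p under 0.05 there were 960 genes with limma and 993 with limma-voom, against 534 expected by chance. That number was 493 without control 2 and 421 without inhibitor 1, both below the chance value, and between 809 and 1272 without each of the other libraries. It was 1700 without both control 1 and inhibitor 4 and 2814 with library weights. In limma with all 8 libraries these were 590 higher and 370 lower, whereas with median-of-ratios scaling they were 449 higher and 540 lower, so the balance of directions depended on the scaling. The values of the 2 groups did not overlap for 5.30% of genes, where chance gives 2.86% on average. Genes vary together, so a single grouping of the libraries can lie far from such averages. Other groupings of the 8 libraries into 4 and 4 gave between 62 and 1730 genes at an unadjusted p under 0.05 by limma. The overlap was not compared in this way, so neither value shows an excess over chance.

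The genes closest to the threshold differed modestly in level. Their groups did not overlap, which a choice by the smallest p favours and which held for 5.3% of all genes. As none passed, the 5 with the smallest p in each direction are given, all with an adjusted p of 0.541 by limma. The ratio of mean RPKM of inhibitor over control lay between 1.26 and 1.65 for the 5 higher and between 0.759 and 0.843 for the 5 lower genes. Slc7a2, a transporter of cationic amino acids that also marks alpha cells, was at 78.2 ± 7.29 RPKM in control and 109 ± 9.89 RPKM in inhibitor cells (SD, n = 4), a log2 fold change of 0.47 ± 0.086 (SE). Crispld1, a secreted cysteine-rich protein, was at 36.0 ± 2.99 and 51.0 ± 6.13 RPKM (SD, n = 4), a log2 fold change of 0.49 ± 0.094 (SE). Gnpda2, an enzyme of glucosamine-6-phosphate breakdown, had a log2 fold change of 0.32 ± 0.056 (SE), and Cxadr, a cell junction protein that serves as a virus receptor, 0.34 ± 0.062 (SE). Nat2, an arylamine acetyltransferase, was at 1.21 ± 0.119 and 1.99 ± 0.165 RPKM (SD, n = 4), levels at which the log2 fold change of 0.44 ± 0.085 (SE) understates the ratio. In the other direction, Uvrag, a protein of autophagy and endosome traffic, was at 19.6 ± 1.13 RPKM in control and 14.97 ± 0.704 RPKM in inhibitor cells (SD, n = 4), a log2 fold change of -0.37 ± 0.063 (SE). Kirrel3, an adhesion protein of the immunoglobulin family, was at 18.1 ± 1.77 and 13.7 ± 0.961 RPKM (SD, n = 4), a log2 fold change of -0.37 ± 0.081 (SE). Rpl28, a protein of the large ribosomal subunit, had a log2 fold change of -0.35 ± 0.073 (SE). Agap1, which acts on Arf GTPases, had -0.31 ± 0.063 (SE), and Ap2a2, a subunit of the clathrin adaptor of endocytosis, -0.24 ± 0.053 (SE). Ribosomal protein genes have many processed pseudogenes, so the reads of Rpl28 are less certain than those of the others.

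**Figure D1:**
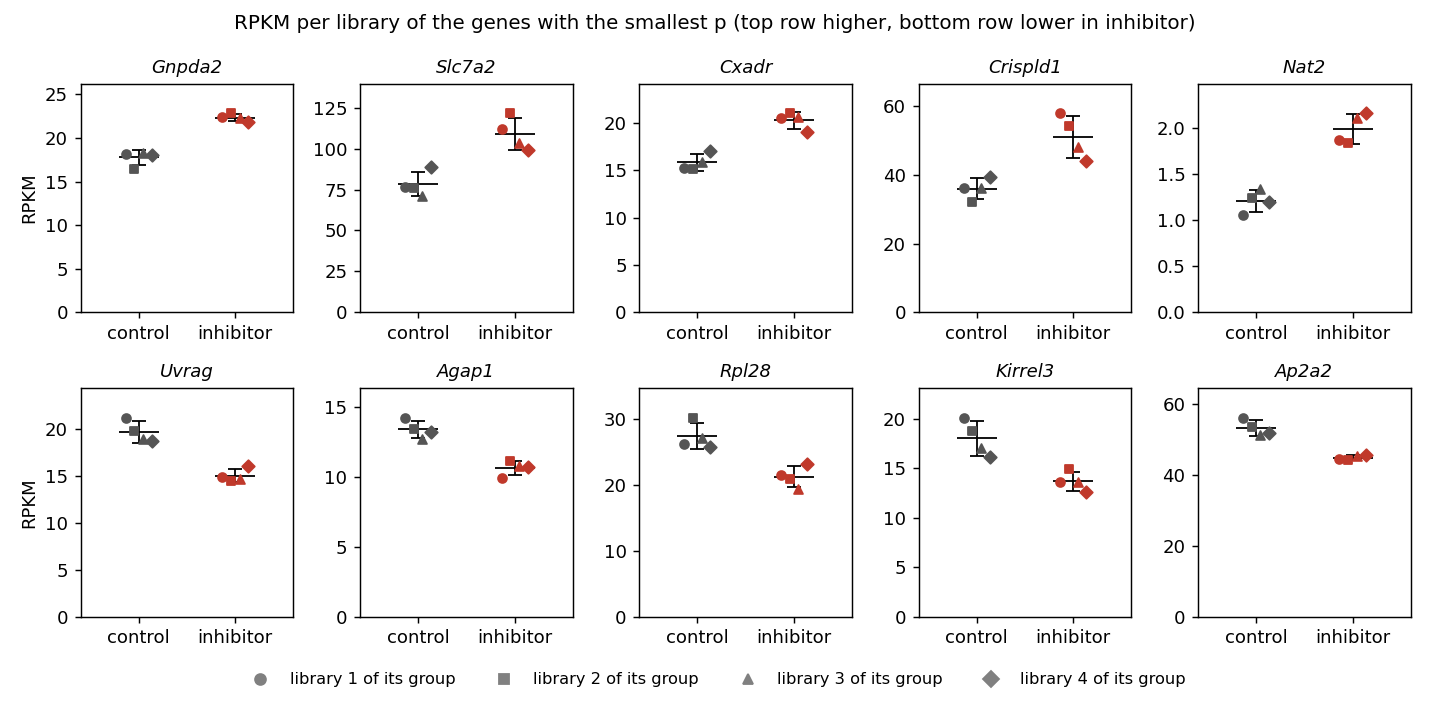
RPKM (vertical axis, from 0) of the 5 genes with the smallest p in each direction in the 4 control and 4 inhibitor libraries. Points are libraries with a marker per library number, wide bars are group means and whiskers are 1 SD. The groups do not overlap for any of the 10 genes, which the choice by the smallest p favours. Each had an adjusted p of 0.541 by limma.

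The authors' deposited table lists 6 genes with an adjusted p under 0.05. These were Slc7a2, Crispld1 and Ero1b with positive and Uvrag, Rpl28 and Agap1 with negative log2 fold changes. Of the 6, 5 are also among the 10 genes above, and Ero1b belongs to the beta-cell genes below. In the authors' deposited table the adjusted p was 0.00629 for Slc7a2 and for Uvrag, 0.0158 for Rpl28 and for Ero1b, 0.0388 for Agap1 and 0.0393 for Crispld1. None of them passed with limma here. The table lists 801 genes at an unadjusted p under 0.05.

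Among 31 measured genes of beta-cell identity and maturity, 18 had a positive and 13 a negative log2 fold change, and the list did not differ as a whole (mean 0.038; camera adjusted p = 0.571). Ero1b, an oxidase that forms disulfide bonds in the endoplasmic reticulum and acts on proinsulin, was at 269.9 ± 38.2 RPKM in control and 382 ± 39.0 RPKM in inhibitor cells (SD, n = 4). Its log2 fold change was 0.51 ± 0.11 (SE), and it was the 1 member past the threshold when adjusted over the list alone, against 0 over all genes. Slc2a2, the main glucose transporter of rodent beta cells, was at 466 ± 36.99 and 568 ± 55.4 RPKM (SD, n = 4), without overlap between the groups (limma adjusted p = 0.541). Neurod1, a transcription factor of endocrine cells, was at 72.8 ± 5.31 and 92.2 ± 17.8 RPKM (SD, n = 4; limma adjusted p = 0.541). Ptprn, a membrane protein of secretory granules, was at 344 ± 41.7 in control and 254 ± 34.3 RPKM in inhibitor cells (SD, n = 4; limma adjusted p = 0.541). Without inhibitor 4 the list mean was 0.10 and passed the test (camera adjusted p = 0.0360), and without inhibitor 2 it was -0.029. It was 0.014 with median-of-ratios scaling, 0.060 with scaling to total reads and 0.0087 with the mesenchymal mean as a covariate. Without both control 1 and inhibitor 4 it was 0.12 (camera adjusted p = 0.00153). The p-values are with the preset correlation, and with an estimated correlation the list over all 8 libraries had an adjusted p of 0.874.

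Genes of stimulus-secretion coupling and exocytosis went both ways, with 16 of 33 positive and 17 negative (mean -0.0018; camera adjusted p = 0.596). The 2 with the smallest p had no overlap between the groups. Stx3, a syntaxin of vesicle fusion, was at 7.04 ± 0.537 and 8.64 ± 0.381 RPKM, and Ergic1, a protein of the compartment between endoplasmic reticulum and Golgi, at 49.9 ± 1.72 and 43.1 ± 0.655 RPKM (SD, n = 4; limma adjusted p = 0.541 for both). The list had 0 members past the threshold over all genes and 0 adjusted over the list alone. Without both control 1 and inhibitor 4 the list mean was 0.069 (camera adjusted p = 0.0257 with the preset correlation), and with an estimated correlation the list over all 8 libraries had an adjusted p of 0.874.

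Of the 34 lists tested, 9 were called by camera with the preset correlation, 2 higher and 7 lower in inhibitor cells. With an estimated correlation 0 of the 9 calls held (adjusted p = 0.874 for each), and with fry 0 held (adjusted p = 0.884 for each). Over all 8 libraries, 0 of the 34 lists passed with either. Without control 3 there were 0 calls, and without inhibitor 2 there was 1. Camera values with libraries left out and under other settings are with the preset correlation. Over the 34 lists, 0 members passed the threshold over all genes. Adjusted over the list alone 1 member passed in each of 5 lists, and each is named with its list. That adjustment does not cover the number of lists, so such members can arise by chance. Ero1b was the member in both the beta-cell identity and the unfolded protein response list, and Slc7a2 and Rpl28 were already named for their small p. The exact permutation p of the list means, unadjusted, was between 0.0857 and 0.629 over the 9 lists. For 7 of the 9 lists the SD between libraries exceeded the difference of the group means in both groups.

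**Figure D2:**
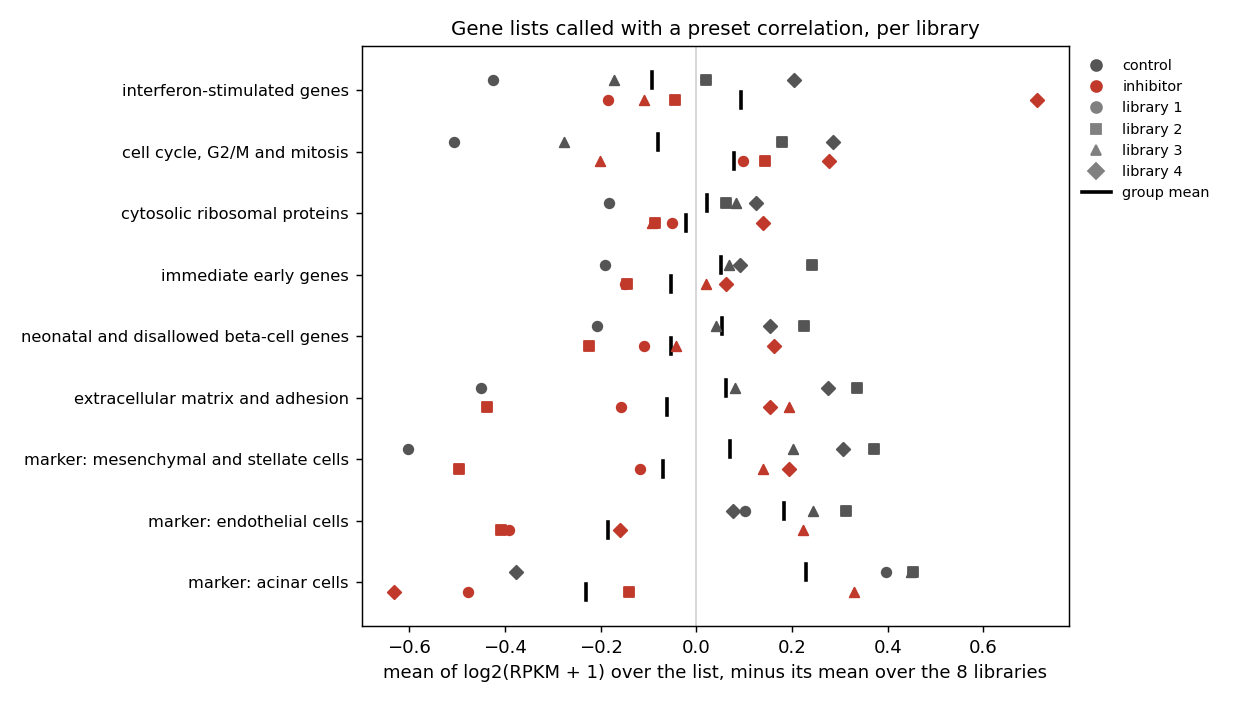
Mean log2(RPKM + 1) of each of the 9 called gene lists per library, minus the mean over the 8 libraries (horizontal axis, log2 units). Grey points are control and red points inhibitor libraries, marker shapes give the library number and black bars the group means; inhibitor 4 stands at 0.71 for the interferon-stimulated genes, while control 1 stands at -0.51 for the G2/M genes and -0.60 for the mesenchymal markers.

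Genes of G2 phase and mitosis lay higher in inhibitor cells, with 66 of 70 members positive and a list mean of 0.16 (camera adjusted p = 0.00859 with the preset and adjusted p = 0.874 with an estimated correlation). Mad2l1, of the spindle checkpoint, was at 8.62 ± 1.39 in control and 10.5 ± 2.05 RPKM in inhibitor cells, Bub1, a kinase of the same checkpoint, at 6.22 ± 2.05 and 7.88 ± 1.49 RPKM, and Nuf2, of the kinetochore, at 8.13 ± 2.27 and 10.1 ± 2.13 RPKM (SD, n = 4). Mki67, the proliferation marker, was at 8.73 ± 2.73 and 9.97 ± 1.85 RPKM (SD, n = 4; limma adjusted p = 0.709). The list mean was lowest in control 1 (-0.51) and control 3 (-0.28). Without control 1 the difference was 0.017 (camera adjusted p = 0.847), and the call was also lost without control 3 (0.093, adjusted p = 0.109), inhibitor 2 (0.14, adjusted p = 0.0929) or inhibitor 4 (0.093, adjusted p = 0.123). It was 0.24, 0.28 and 0.25 without control 2, control 4 and inhibitor 3, and -0.050 without both control 1 and inhibitor 4. With library weights it was 0.0016 (camera adjusted p = 0.986). With the mesenchymal mean as a covariate it was 0.22 ± 0.20 (SE), and camera with the preset correlation still called the list. Of 48 genes of S phase and DNA replication, 40 were positive, with a mean of 0.094 that did not pass (camera adjusted p = 0.0953). Ccne2, a cyclin of S phase entry, was at 3.20 ± 0.780 and 4.14 ± 0.579 RPKM and Slbp, which binds histone mRNAs, at 16.0 ± 1.22 and 18.4 ± 2.55 RPKM (SD, n = 4). The S phase list passed without control 2, control 4 or inhibitor 3 (0.15, 0.17 and 0.17; camera adjusted p = 0.00384, 0.00152 and 0.00101), with median-of-ratios scaling (adjusted p = 0.0398) and with the mesenchymal mean as a covariate (0.13, adjusted p = 0.0166). Its mean was 0.0075 without control 1 (adjusted p = 0.910), 0.051 without control 3 (adjusted p = 0.403), 0.048 without inhibitor 4 (adjusted p = 0.492) and -0.038 without both control 1 and inhibitor 4. The G1 cyclins and CDK inhibitors had 11 of 16 members positive (mean 0.075; camera adjusted p = 0.180), with a mean of 0.031 without control 1 and 0.044 without control 3.

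Genes of the extracellular matrix and adhesion lay lower in inhibitor cells, with 47 of 56 members negative and a mean of -0.12 (camera adjusted p = 0.00859 with the preset and adjusted p = 0.874 with an estimated correlation). Eln, which encodes elastin, was at 355 ± 114 and 235 ± 179 RPKM, Loxl1, an elastin crosslinking enzyme, at 32.5 ± 7.31 and 24.3 ± 3.94 RPKM, and Itga6, a laminin receptor subunit, at 5.26 ± 0.557 and 4.45 ± 0.438 RPKM (SD, n = 4). Markers of mesenchymal and stellate cells lay lower as well, with 19 of 23 negative and a mean of -0.14 (camera adjusted p = 0.0459 with the preset and adjusted p = 0.874 with an estimated correlation). S100a4, a calcium-binding protein of fibroblasts, was at 96.4 ± 21.3 and 75.2 ± 22.9 RPKM and Ngfr, a neurotrophin receptor of stellate cells, at 1.95 ± 0.952 and 1.21 ± 0.407 RPKM. Has2, which makes hyaluronan, went the other way, at 1.67 ± 0.710 and 2.51 ± 0.613 RPKM (SD, n = 4). The mesenchymal mean was lowest in control 1 (-0.60) and inhibitor 2 (-0.50). Without inhibitor 2 both list means were 0.0023 and 0.0022 (camera adjusted p = 0.538 and 0.633). Without control 1 they were -0.29 and -0.36, without both control 1 and inhibitor 4 they were -0.37 and -0.45, and with library weights -0.33 and -0.36. The matrix call was also lost without control 2 (-0.031, adjusted p = 0.0841), control 3 (-0.12, adjusted p = 0.0688) or control 4 (-0.051, adjusted p = 0.0557), and the mean was -0.21 without inhibitor 3 and -0.20 without inhibitor 4. The mesenchymal call was also lost without control 2 (-0.040, adjusted p = 0.223), control 3 (-0.095, adjusted p = 0.309), control 4 (-0.061, adjusted p = 0.225) or inhibitor 1 (-0.12, adjusted p = 0.0666), with limma-voom (adjusted p = 0.0522), with median-of-ratios scaling (adjusted p = 0.0924) and with at least 10 reads in all 8 libraries (adjusted p = 0.0515). Its mean was -0.21 without inhibitor 3 and -0.23 without inhibitor 4. With the mesenchymal mean as a covariate, the matrix difference was -0.0074 (camera adjusted p = 0.792).

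Neonatal genes and genes normally kept low in mature beta cells lay lower in inhibitor cells, with 23 of 27 members negative and a mean of -0.11 (camera adjusted p = 0.0196 with the preset and adjusted p = 0.874 with an estimated correlation). Igfbp4, which binds insulin-like growth factors, was at 19.4 ± 5.56 and 15.1 ± 3.00 RPKM and Ndrg4 at 120.4 ± 8.61 and 109.5 ± 3.12 RPKM (SD, n = 4). The call was lost without control 2 (-0.050, adjusted p = 0.0748), control 3 (-0.11, adjusted p = 0.0829), control 4 (-0.074, adjusted p = 0.0557) or inhibitor 2 (-0.050, adjusted p = 0.311), and with the mesenchymal mean as a covariate (-0.048, adjusted p = 0.0847). Without control 1 or inhibitor 4 the mean was -0.19 or -0.18, without both it was -0.27, and with library weights -0.23.

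Immediate early genes, which respond within minutes to stimuli, had 23 of 31 members negative and a mean of -0.10 (camera adjusted p = 0.00900 with the preset and adjusted p = 0.874 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, was at 26.0 ± 3.43 in control and 18.8 ± 4.98 RPKM in inhibitor cells, and Csrnp1 at 8.54 ± 1.33 and 6.53 ± 1.37 RPKM (SD, n = 4). Arc, an activity-regulated gene, was at 6.02 ± 1.90 and 4.16 ± 0.462 RPKM (SD, n = 4), with no overlap between the groups. The call was lost without control 2 (-0.042, adjusted p = 0.0569), control 3 (-0.10, adjusted p = 0.0784) or inhibitor 2 (-0.074, adjusted p = 0.151), and with the mesenchymal mean as a covariate (-0.056, adjusted p = 0.0849). Without control 1 the mean was -0.19, without both control 1 and inhibitor 4 it was -0.22, and with library weights -0.23.

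Interferon-stimulated genes lay higher in inhibitor cells, with 44 of 49 members positive and a mean of 0.19 (camera adjusted p = 0.00900 with the preset and adjusted p = 0.874 with an estimated correlation). The difference rested on inhibitor 4 and in part on control 1. The list mean was 0.71 in inhibitor 4 and between -0.19 and -0.045 in the other inhibitor libraries, against -0.42 to 0.20 in control libraries. Without inhibitor 4 the difference was -0.020 (camera adjusted p = 0.874). The call was also lost without control 1 (0.076, adjusted p = 0.184) or control 3 (0.16, adjusted p = 0.0688), the mean was 0.28 without control 4, and without both control 1 and inhibitor 4 it was -0.13 and passed as lower (adjusted p = 0.0382). With library weights it was -0.060 (adjusted p = 0.780). Irgm, an interferon-induced GTPase, was at 6.88 ± 1.59 and 9.64 ± 2.78 RPKM, and Cmpk2, a mitochondrial nucleotide kinase, at 1.51 ± 0.288 and 2.17 ± 0.655 RPKM (SD, n = 4). Ifi44l was at 2.14 ± 0.487 and 3.16 ± 0.609 RPKM (SD, n = 4) with no overlap between the groups (limma adjusted p = 0.541). The genes of NF-kappaB and inflammation had 18 of 22 members positive and a mean of 0.19 that did not pass (camera adjusted p = 0.139), with 0.73 in inhibitor 4. Their mean was -0.025 without inhibitor 4 and 0.055 without control 1 (adjusted p = 0.715), and passed without inhibitor 1 (0.30, adjusted p = 0.00127) and with the mesenchymal mean as a covariate (0.27, adjusted p = 0.0166).

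Cytosolic ribosomal protein genes lay slightly lower in inhibitor cells, with 36 of 55 members negative and a mean of -0.045 (camera adjusted p = 0.0459 with the preset and adjusted p = 0.874 with an estimated correlation). Rpl28 was at 27.3 ± 1.97 and 21.2 ± 1.57 RPKM and was the 1 member past the threshold when adjusted over the list alone, against 0 over all genes. Rpl31 was at 8.56 ± 1.24 and 6.45 ± 1.01 RPKM and Rps15 at 258 ± 32.8 and 213 ± 11.7 RPKM (SD, n = 4). The call was lost without control 3 (-0.024, adjusted p = 0.406), control 4 (-0.010, adjusted p = 0.228), inhibitor 1 (-0.035, adjusted p = 0.0744), inhibitor 2 (-0.023, adjusted p = 0.446) or inhibitor 3 (-0.021, adjusted p = 0.122), with limma-voom (adjusted p = 0.0558), with at least 10 reads in all 8 libraries (adjusted p = 0.0515) and with the mesenchymal mean as a covariate (-0.0082, adjusted p = 0.384). The mean was -0.11 without control 1, -0.098 without inhibitor 4, -0.17 without both, -0.11 with library weights, -0.068 with median-of-ratios scaling and -0.024 with scaling to total reads. Genes of tRNA processing, modification and cleavage had 39 of 61 members positive (mean 0.042; camera adjusted p = 0.244). Ssb, the La protein that binds the ends of new tRNAs, was at 23.4 ± 1.76 and 27.2 ± 1.26 RPKM, and Wdr4, a subunit of a tRNA methyltransferase, at 2.55 ± 0.327 and 1.90 ± 0.192 RPKM (SD, n = 4; limma adjusted p = 0.541 for both). The cytosolic aminoacyl-tRNA synthetases had 11 of 19 members positive (mean 0.0042; camera, which placed them below other genes, adjusted p = 0.772). The unfolded protein response had 26 of 37 members negative (mean -0.023; camera adjusted p = 0.117), among them Crebzf at 16.4 ± 1.64 and 13.9 ± 1.19 RPKM (SD, n = 4), and Ero1b was its 1 member past the threshold when adjusted over the list alone. That list passed without control 2 (-0.037, adjusted p = 0.0154) or control 4 (-0.056, adjusted p = 0.00152) and with the mesenchymal mean as a covariate (-0.037, adjusted p = 0.0295), and its mean was 0.010 without control 1 and -0.011 without control 3. The ATF4 targets had 29 of 41 members negative (mean -0.032; camera adjusted p = 0.102) and passed without control 1 (-0.091, adjusted p = 0.00346) and without both control 1 and inhibitor 4 (-0.10, adjusted p = 0.00714). Their mean was -0.0026 without control 4 (adjusted p = 0.225), -0.0094 without control 2 (adjusted p = 0.103) and -0.021 without inhibitor 2 (adjusted p = 0.307).

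Markers of other cell types differed between libraries of both groups. Only few of the markers fixed for some cell types could be tested. These were 5 of 30 endothelial, 4 of 41 acinar and 5 of 40 macrophage and leukocyte markers. Of the endothelial markers, 5 of 5 were negative (mean -0.37; camera adjusted p = 0.0137 with the preset and adjusted p = 0.874 with an estimated correlation). Plvap, of fenestrated endothelium, was at 4.38 ± 2.16 and 1.81 ± 1.24 RPKM, Egfl7 at 2.51 ± 0.538 and 2.00 ± 0.194 RPKM, and Eng, a receptor for TGF-beta ligands, at 40.9 ± 10.5 and 33.2 ± 4.92 RPKM (SD, n = 4). The endothelial mean was 0.10, 0.31, 0.24 and 0.076 in control 1 to 4 and -0.39, -0.41, 0.22 and -0.16 in inhibitor 1 to 4. Inhibitor 3 thus lay above control 1 and control 4. The endothelial call was lost without control 3 (-0.35, camera adjusted p = 0.0829) or inhibitor 2 (-0.29, camera adjusted p = 0.151). Acinar markers had 4 of 4 members negative (mean -0.46; camera adjusted p = 0.0358 with the preset and adjusted p = 0.874 with an estimated correlation), largely through Ctrb1, which encodes a chymotrypsinogen. Ctrb1 was at 9.80, 10.2, 11.5 and 0.92 RPKM in control 1 to 4 and at 0.691, 2.66, 10.4 and 0.177 RPKM in inhibitor 1 to 4. Ctrl, a chymotrypsin-like protease, was at 2.75 ± 0.333 and 2.42 ± 0.218 RPKM (SD, n = 4). The acinar call was lost without control 1 (-0.41, adjusted p = 0.162), control 3 (-0.39, adjusted p = 0.0829), inhibitor 1 (-0.38, adjusted p = 0.0651), inhibitor 2 (-0.49, adjusted p = 0.0929) or inhibitor 4 (-0.33, adjusted p = 0.110), without both control 1 and inhibitor 4 (-0.27, adjusted p = 0.388), with library weights (-0.51, adjusted p = 0.0794) and with median-of-ratios scaling (adjusted p = 0.0508). With at least 10 reads in all 8 libraries, which removed Ctrb1, its mean was -0.19 (adjusted p = 0.0776). Delta-cell markers had 5 of 5 members negative (mean -0.18; camera adjusted p = 0.0953). Sst was at 769 ± 207 and 533 ± 94.4 RPKM and Hhex, a transcription factor of delta cells, at 3.61 ± 0.727 and 3.15 ± 0.204 RPKM (SD, n = 4). That list passed without control 2 (-0.21, adjusted p = 0.0207) or control 4 (-0.22, adjusted p = 0.0405) and with the mesenchymal mean as a covariate (-0.22, adjusted p = 0.0166). Over all 8 libraries the delta-cell list had a camera adjusted p of 0.874 with an estimated correlation. Its mean was -0.10 without control 1 (adjusted p = 0.595), -0.052 without both control 1 and inhibitor 4 (adjusted p = 0.947) and -0.080 with library weights (adjusted p = 0.692). Alpha-cell markers had 5 of 14 members positive (mean -0.057; camera adjusted p = 0.238), with Slc7a2 as the 1 member past the threshold adjusted over the list alone and Sstr2, a somatostatin receptor, at 6.88 ± 1.20 and 5.56 ± 0.398 RPKM (SD, n = 4). Gcg itself was at 7599 ± 1148 and 7933 ± 1237 RPKM (SD, n = 4). Markers of PP and epsilon cells (2 of 5 positive; adjusted p = 0.772), duct cells (10 of 18, mean 0.027, though placed below other genes by camera; adjusted p = 0.734), macrophages and leukocytes (4 of 5; adjusted p = 0.388) and Schwann cells and neurons (2 of 7; adjusted p = 0.772) did not pass with camera. In the last list Elavl4 was the 1 member past the threshold adjusted over the list alone, at 9.06 ± 0.710 and 12.4 ± 1.72 RPKM (SD, n = 4), and it was named after its value was seen.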

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

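The tests of the interferon-stimulated genes in inhibitor 4 were chosen after the result was seen. In 13 of 184 groups of 4 libraries, 1 library stood far from the other 3 relative to the range of the group, where chance alone gives about 1 in 20 groups, or 9 here. Of the 13, 4 were values of control 1, 3 of control 4, 3 of inhibitor 4, 2 of inhibitor 3 and 1 of control 2.

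Interferon-stimulated genes had a list mean of 0.71 in inhibitor 4, far above the other inhibitor libraries (-0.19 to -0.045). Relative to the control mean, inhibitor 1 to 3 lay at -0.020 ± 0.14 (SE), whereas inhibitor 4 lay at 0.80. An effect of the size seen in inhibitor 4 was thus not present in the other inhibitor libraries. Whether the inhibitors had a smaller effect on all libraries that received them cannot be told. Inhibitor 4 was set aside for its high value, so the rest had to lie lower, and the SE leaves room for the list mean of 0.19. Leukocytes carried into inhibitor 4 cannot be told apart from other explanations, since its macrophage and leukocyte markers (5 genes) lay 0.033 (0.0332) above the mean of the other libraries, whose SD was 0.19, and 4 of the 5 were at no more than 4.45 RPKM in any library. Inhibitor 4 held few cells of male animals, unlike every other library. The Y-linked genes Eif2s3y (0.257 RPKM, 15 reads) and Kdm5d (0.12 RPKM, 18 reads) were at least 23.1-fold lower there than in each other library. Its animals thus differed in sex, at least in their mix, from those of the other libraries. Whether that difference of animals explains the interferon-stimulated genes stays open. An effect of the inhibitors that was limited to inhibitor 4, or a difference in its culture, was not tested.

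Other values that stood apart were as follows. Glucagon took 1.45% of reads in inhibitor 4, against 1.07% to 1.12% in the other inhibitor libraries, and the genes of glycolysis and hypoxia had a list mean of 0.20 (0.1975) there, against -0.088 to -0.070. In control 1, the mean was 0.095 for stimulus-secretion coupling and exocytosis, -0.14 (-0.1427) for mitochondrial ribosomal proteins and -0.16 (-0.1619) for fatty acid oxidation, against ranges of -0.038 to -0.019, 0.019 to 0.040 and 0.0086 to 0.035 in the other control libraries. Egfl7 was at 1.71 RPKM in control 1, against 2.70 to 2.83. In control 4, Ctrb1 was at 0.92 RPKM (0.92001), against 9.80 to 11.5 in the other control libraries, the acinar markers had a mean of -0.38 (-0.3758), against 0.40 to 0.45, and Ptprn was at 281 RPKM, against 359 to 369.9. In inhibitor 3, Loxl1 was at 30.1 RPKM, against 22.03 to 22.7, and cholesterol biosynthesis had a mean of -0.20 (-0.1979), against 0.082 to 0.10. Gnpda2 was at 16.5 RPKM in control 2, against 18.1 to 18.3 in the other control libraries.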

How the results depend on the processing

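Library weights, the mesenchymal covariate and leaving out both control 1 and inhibitor 4 were chosen after the data were seen. The count of genes passing was 0 higher and 0 lower under all 20 alternatives run, with the added minimum fold of 1.5 too, and the smallest adjusted p over them was 0.0959 (library weights). The number of lists called with camera was 9, between 6 and 12 under the other settings that left out no single library, 0 with an estimated correlation, 0 with fry, and between 0 (without control 3) and 10 (without inhibitor 3) when a library was left out. The libraries were treated as unpaired, as fixed beforehand, since the labels do not say that the replicate numbers mark shared cultures. In addition, 1 of the pairs did not vary together. For number 4 a shared pool of cells is argued against, as Eif2s3y was at 8.915 RPKM in control 4 and 0.257 RPKM in inhibitor 4. For the other numbers the question is open. There Eif2s3y was at 14.2 and 18.8, 6.96 and 6.86, and 8.48 and 9.26 RPKM in control and inhibitor libraries 1 to 3. Deviations from the group means correlated at 0.14, -0.27, 0.32 and 0.45 within pairs 1 to 4, and 5 of 8 libraries correlated best with their own number, which is a hint from the data only. With the replicate block 0 genes were higher, 0 lower and 12 lists were called. The block added calls of the S phase (adjusted p = 0.0230), NF-kappaB (adjusted p = 0.0267) and delta-cell lists (adjusted p = 0.0366) and changed no other call. The planned DESeq2 test was not run, and limma-voom on the recovered reads took its place. In addition, no mitochondrially encoded mRNA could be removed.

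Of 53 named genes, 50 kept their direction under the alternatives and 0 passed the threshold under any of them. Of 34 lists, 12 kept the sign of their mean. Signs turned as follows, and the cause was not tested except for the scalings, which shifted all genes alike and so turned list means near 0. The median log2 fold change was 0.015, and it was -0.0070 with median-of-ratios scaling, 0.035 with scaling to total reads and 0.024 with the insulin genes removed besides. Without both control 1 and inhibitor 4 the log2 fold change was 0.066 for Ins2, -0.15 for Gcg and -0.030 for Mki67, and list means were 0.069 for exocytosis, -0.038 for S phase, -0.050 for G2/M, -0.017 for p53 targets, -0.082 for apoptosis, -0.024 for tRNA synthetases, -0.028 for mitochondrial ribosomal proteins, -0.053 for oxidative phosphorylation, -0.0014 for the TCA cycle, -0.13 for interferon-stimulated genes, -0.16 for NF-kappaB genes, -0.0068 for fatty acid oxidation and -0.058 for duct markers. With library weights these were 0.0099 for Ins2, -0.095 for Gcg, -0.023 for Mki67, 0.032 for exocytosis, -0.0041 for p53 targets, -0.043 for apoptosis, -0.0051 for tRNA synthetases, -0.027 for oxidative phosphorylation, -0.060 for interferon-stimulated genes, -0.092 for NF-kappaB genes, -0.039 for duct markers and -0.065 for leukocyte markers. Scaling to total reads gave 0.019 for exocytosis, 0.0048 for PP and epsilon markers and 0.011 for Schwann cell and neuron markers, and with the insulin genes removed besides, 0.0070 for exocytosis and 0.00078 for Schwann cell and neuron markers. Median-of-ratios scaling gave -0.020 for tRNA synthetases and -0.019 for oxidative phosphorylation. The mesenchymal covariate gave 0.016 for glycolysis and 0.025 for PP and epsilon markers.

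With each library left out in turn, the difference in the share of reads was between -1.72 and 0.209 percentage points for insulin, -0.019 and 0.106 for Gcg, -0.025 and -0.011 for Sst, and -0.00095 and 7.03e-05 for Ppy. The log2 fold change was between -0.21 and 0.055 for Ins2 and between -0.051 and 0.11 for Gcg. List means were between -0.029 and 0.10 for beta-cell identity, -0.035 and 0.038 for exocytosis, -0.022 and 0.094 for apoptosis, -0.056 and 0.010 for the unfolded protein response, -0.012 and 0.020 for tRNA synthetases, -0.012 and 0.058 for mitochondrial ribosomal proteins, -0.045 and 0.036 for oxidative phosphorylation, -0.091 and 0.019 for glycolysis, -0.013 and 0.11 for cholesterol biosynthesis, -0.020 and 0.28 for interferon-stimulated genes, -0.025 and 0.30 for NF-kappaB genes, -0.29 and 0.0023 for extracellular matrix, -0.11 and 0.025 for PP and epsilon markers, -0.038 and 0.081 for duct markers, -0.36 and 0.0022 for mesenchymal markers, and -0.026 and 0.012 for Schwann cell and neuron markers. Without a change of sign they were between 0.0075 and 0.17 for S phase, 0.017 and 0.28 for G2/M, 0.031 and 0.13 for G1, 0.014 and 0.081 for p53 targets, -0.091 and -0.0026 for ATF4 targets, 0.024 and 0.066 for tRNA processing, 0.015 and 0.054 for the TCA cycle, 0.0093 and 0.075 for fatty acid oxidation, -0.084 and -0.0059 for Wnt, -0.17 and -0.022 for Notch, -0.075 and -0.022 for alpha-cell markers, -0.22 and -0.10 for delta-cell markers, and 0.024 and 0.18 for leukocyte markers. The lowest count in a library was 4 reads for Ctrb1, 15 for Eif2s3y and 18 for Kdm5d, and it was at least 34 for the other genes named by the rule.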

Other observations

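The tests of the number of genes over other splits and of the mesenchymal marker mean were chosen after the data were seen.

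Genes of energy metabolism did not differ between the groups as lists. Oxidative phosphorylation had 38 of 68 nuclear-encoded members positive (mean 0.0044; camera, which placed them below other genes, adjusted p = 0.883), the TCA cycle and pyruvate metabolism 24 of 38 (mean 0.034; adjusted p = 0.416), fatty acid oxidation 20 of 28 (mean 0.054, and 0.0093 without control 1; adjusted p = 0.131) and mitochondrial ribosomal proteins 45 of 71 (mean 0.030; adjusted p = 0.397). Glycolysis and hypoxia targets had 20 of 34 members negative (mean -0.022, adjusted p = 0.197). With the preset correlation they passed without inhibitor 4 (-0.091, adjusted p = 0.0255) and without both control 1 and inhibitor 4 (-0.15, adjusted p = 0.00144). Their mean was 0.019 without control 2 and 0.0092 without control 4. Over all 8 libraries the glycolysis list had a camera adjusted p of 0.874 with an estimated correlation. Cholesterol biosynthesis had 15 of 23 members positive (mean 0.042; adjusted p = 0.745) and passed without control 1 (0.098, adjusted p = 0.0398), while the mean was -0.013 without control 3.

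Genes of signalling and cell death likewise did not pass. Notch, TGF-beta and BMP signalling had 21 of 33 members negative (mean -0.084, camera adjusted p = 0.0777). With the preset correlation it passed without control 1 (-0.17, adjusted p = 0.00369), inhibitor 3 (-0.13, adjusted p = 0.00158) or inhibitor 4 (-0.12, adjusted p = 0.0360). It also passed without both control 1 and inhibitor 4 (-0.20, adjusted p = 0.00153) and with library weights (-0.20, adjusted p = 0.00395). The same held with scaling to total reads (adjusted p = 0.0378) and with the insulin genes removed besides (adjusted p = 0.0417). Over all 8 libraries the Notch list had an adjusted p of 0.874 with an estimated correlation. Its mean was -0.022 without inhibitor 2 (adjusted p = 0.538), -0.028 without control 2 (adjusted p = 0.171) and -0.026 with the mesenchymal mean as a covariate (adjusted p = 0.376). The Wnt pathway had 19 of 34 members negative (mean -0.039, and -0.0059 without control 4; adjusted p = 0.317). Regulators of apoptosis had 23 of 34 members positive (mean 0.049; adjusted p = 0.388) and p53 targets 18 of 32 (mean 0.050, and 0.014 without control 1; adjusted p = 0.323).

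Chance cannot be excluded for the list calls. Of the 35 splits of the 8 libraries into 4 and 4, 29 called as many lists with camera as the 9 of the real split, and the highest other split called 18. As the real split called 0 genes in each direction, 35 of 35 splits gave as many whatever the data, so this count says nothing about chance. The highest other split called 1 gene. By the number of genes at an unadjusted p under 0.05 the real split stood at rank 8 with 960 genes. The split at rank 1 set control 1 to 3 and inhibitor 3 against the remaining libraries, with 1730 genes, and Ctrb1 was at 9.80 to 11.5 RPKM in the former and at 0.177 to 2.66 RPKM in the latter. The first principal component of the log2 values held 41.2% of the variance and placed control 1 at -24.3 and inhibitor 4 at 17.4, the ends of its range.

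Over the libraries, the level of the extracellular matrix genes went with that of the mesenchymal markers. With the mesenchymal marker mean as a covariate the difference of the matrix list, which shared 0 genes with the markers, was -0.0074 ± 0.047 (SE). Without the covariate it was -0.12 ± 0.23 (SE). As that difference lay within its SE, no lower level in inhibitor cells was shown whose source could be judged. The part that went with the markers was -0.12, with an SE of 0.0096 from the slope on the markers alone. That SE takes the group difference of the marker mean, -0.14, as exact. The marker difference was 0.0022 without inhibitor 2, and the SE does not cover this spread. For the neonatal and disallowed beta-cell list, without the 1 gene on both lists, the difference was -0.046 ± 0.052 (SE) with the covariate. The unadjusted difference was -0.10 ± 0.12 (SE), also within its SE. The share of mesenchymal cells cannot be told apart from other explanations there. The part that went with the markers, -0.057 ± 0.010 (SE from the slope alone, as above), was close to the part that stayed. The covariate does not separate fewer mesenchymal cells from lower expression in the same number of cells. An effect of the inhibitors on those cells stays open, and the low values of control 1 show that mesenchymal markers also varied without inhibitor.

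The difference of the G2/M genes was 0.16 ± 0.21 (SE), and 0.017 without control 1. As control 1 had the lowest value, leaving it out had to shrink the difference, so this tests no explanation. With the mesenchymal marker mean as a covariate the difference was 0.22 ± 0.20 (SE), so it did not shrink in these libraries. The part that went with the markers was -0.060 ± 0.040 (SE from the slope alone), opposite in sign to the difference. That SE takes the marker difference as exact, and the marker difference was 0.0022 without inhibitor 2. As the G2/M difference lay within its own SE, a different share of mesenchymal cells cannot be judged as its source. An effect of the inhibitors on proliferation is neither shown nor excluded.

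The Y-linked transcripts show a pattern over library numbers that the labels do not explain. Eif2s3y was at 14.2 RPKM in control 1 and 18.8 in inhibitor 1, at 6.96 and 6.86 in the libraries numbered 2, and at 8.48 and 9.26 in those numbered 3, but at 8.91 in control 4 and 0.257 in inhibitor 4. Kdm5d followed the same order, at 7.04 and 8.73, 3.46 and 2.77, 3.65 and 4.08, and 3.83 and 0.12 RPKM.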
